A study of Mus musculus with 4 samples.

How the data were processed

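Single-cell RNA sequencing of whole mouse pituitary was deposited for 4 libraries, 2 from mice on a high-fat diet (HFD) and 2 from mice on a normal diet (ND). Per the labels, the mice were 4 weeks old at the start, the diets lasted 12 weeks, and each library pooled 3 pituitaries. The labels also name a gonadotroph cell line and cell type for every library, although tissue and protocol describe the whole gland. The cells were treated here as whole pituitary.

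The deposited values are UMI counts per gene and barcode, in a single matrix of all libraries. Per the file headers, the matrix was written by Cell Ranger 8.0.1. Seurat is named without a version or role per the submitters' processing notes. The genome build, annotation, read length and aligner settings are not given in the sources used here. The deposited gene table pairs 55357 Ensembl identifiers with symbols. Of these identifiers, 52081 are in GENCODE vM21 (GRCm38) and 49847 have the same symbol there. That annotation was used only to compare transcript sequences and gene overlaps. Where several identifiers share a symbol, the one with the most UMIs was used.

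Each barcode ends in a number from 1 to 4, and nothing in the files or labels says which library a number stands for. No cell was therefore assigned to a library or a diet. The matrix was treated as 1 pooled sample, and the planned HFD and ND comparisons were not made, as had been set for this case before the data were examined. No test between groups was run and no p-value is given. The 4 barcode groups are called sets 1 to 4. They are not replicates of a group, so values are given pooled and as the range over the sets.

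Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 25% mitochondrial UMIs, which removed 567 of 40406. Doublets were called with Scrublet in scanpy 1.11.5 for each set at its automatic threshold. It marked 3833 barcodes (9.62%), from 8.89% to 11.2% per set, and these were removed. Counts of the remaining 36006 cells were scaled to 10000 per cell and log transformed. Clusters came from 2000 variable genes chosen within sets, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9), without integration of the sets.

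Clusters were named from markers of 23 cell types fixed before the data were examined. The naming thresholds were set after seeing the data. A name needed at least 3 markers with a log2 fold of 0.5 or more over all other cells and detection in at least 25% of cells. Clusters with markers of 2 classes, more markers of another class among the top 10 genes, or few UMIs without an own marker in that top 10 stayed unnamed. Names describe clusters rebuilt here.

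Counts were summed per class and set and given as CPM of the UMI sum of that class with exact Poisson intervals. Shares of cells have exact Clopper-Pearson intervals. Both are 95% intervals and cover counting error only. The floor for a gene without counts was 3 counts. The planned rule for named genes needed a diet test and could not be used. It was replaced, after seeing the data, by a rule on the class in which a gene of the fixed lists had its highest CPM. A gene counted as peaking in a class when that class led in each of the 4 sets, among the 12 classes with at least 20 cells in every set (all but pituicyte-like) and with at least 20 counts in the leading class. Up to 3 genes were named for each of the 2 leading classes of a list. They had at least 100 counts, were not naming markers, and led in the same class with the 7 hormone genes left out of library sizes. They were ranked by fold over the next class. Some genes that met this rule are not reported here. Hormone genes and the hormone receptors were named as planned. Peak classes were found only for list genes, naming markers, hormone genes and receptors. No list count is therefore set beside the share of all genes that peak in a class.

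Both steps were tested on simulated data. Of 8000 cells drawn from the class profiles, 99.9% got their class back. These cells came from the classes named here, without unnamed cells, doublets, or variation in profile within a class or between sets. Near-complete recovery was thus built in, and it does not measure how well real cells were named. For the peak rule, run on 12691 genes, 86 of 100 genes raised 4.0-fold in 1 class were recovered in all 4 sets, and 14 of 100 raised 1.5-fold. Of 12491 genes level in all classes, 0.881% met the rule. The counts simulated for the peak rule likewise had no differences between sets beyond sampling. Alternatives kept the doublets, used a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), used resolution 0.5, gave cells to classes by marker score, left out hormone genes, equalised cells per set, thinned the counts, subtracted free RNA or left out each set. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.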

Results

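Whole-pituitary cells were profiled in 4 libraries of 3 pooled mouse pituitaries, 2 from mice on a high-fat diet and 2 from mice on a normal diet. The diet comparison could not be made, because the barcodes of the shared matrix carry set numbers that no label ties to a diet. The cell classes of the gland and their transcripts are therefore described over all 4 sets. The matrix held 346690898 UMIs in 40406 barcodes. Sets 1 to 4 held 84470879, 92665029, 87933632 and 81621358 UMIs in 10169, 10096, 10212 and 9929 barcodes. Median UMIs per barcode ranged from 7167 to 8070.5. No replicate error is available for any value, and intervals cover counting error only.

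Somatotroph-like cells, the growth hormone class, made up 38.2% of the 36006 kept cells (95% interval 37.7 to 38.7), from 36.6% to 40.04% over the sets. Lactotroph-like cells, the prolactin class, followed with 23.5% (23.0 to 23.9), from 19.8% to 25.9%. Corticotroph-like cells made up 7.29% and melanotroph-like cells 1.83%. Gonadotroph-like cells, the class named in the labels, were 869 cells or 2.41% (2.26 to 2.58), and thyrotroph-like cells 1.86%. The non-endocrine classes were stem or folliculostellate-like (5.31%), macrophage or microglia-like (4.61%), endothelial-like (3.02%), T or NK cell-like (1.31%), fibroblast-like (1.16%), pituicyte-like (0.630%) and B cell-like (0.383%). Of 1659 macrophage or microglia-like cells, 414 formed a cluster with a median of 814.5 UMIs. Of 1912 stem or folliculostellate-like cells, 295 formed a cluster with a median of 752 UMIs. Both medians lie below that of the unnamed cluster 8 described below (1386.5 UMIs), and whether these barcodes are intact cells was not tested. By marker score fibroblast-like, pituicyte-like and B cell-like cells were 2.31%, 1.06% and 3.34%. Of the kept cells, 8.50% stayed unnamed. No cluster met the naming rule for proliferating cells.

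Several classes differed between sets by more than counting error. Gonadotroph-like cells ranged from 1.31% to 4.18%, a 3.19-fold span, with 117 cells in set 1 and 373 in set 2. Melanotroph-like cells ranged from 1.12% to 2.94% and pituicyte-like cells, glia of the posterior lobe, from 0.0672% to 1.05%. The somatotroph-like and lactotroph-like shares also differed beyond their intervals, by 1.09-fold and 1.31-fold. B cell-like shares, from 0.312% to 0.435%, had overlapping intervals. The gonadotroph-like share was 4.24% at resolution 0.5, where thyrotroph-like cells had no class of their own, and the thyrotroph-like share was 4.60% by marker score.

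**Figure D1:**
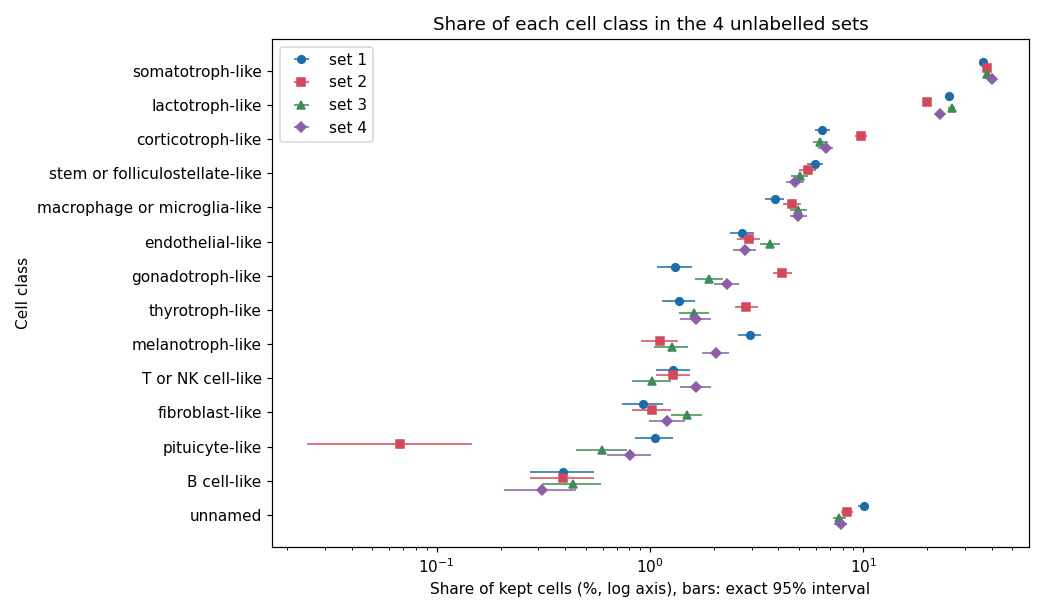
Share of kept cells (%, log axis) in each cell class, with 1 symbol per unlabelled set and exact 95% intervals as bars. Somatotroph-like cells lie between 36.6% and 40.04% in every set, and gonadotroph-like cells between 1.31% and 4.18%.

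Hormone transcripts, which also served as naming markers, ranged widely in level between their classes. Gh reached 442192 CPM in somatotroph-like cells and from 404341 to 463609 CPM over the sets. Prl reached 202091 CPM in lactotroph-like cells (172038 to 218967). Pomc, the precursor of ACTH and MSH, was 185705 CPM in melanotroph-like cells and 55157 CPM in corticotroph-like cells. In gonadotroph-like cells Cga, the alpha subunit shared by the glycoprotein hormones, stood at 91569 CPM. There the beta subunits Fshb and Lhb stood at 8636 and 748 CPM, and Lhb ranged from 454 to 858 CPM over the sets. The Lhb level is uncertain, since 2 identifiers carry that symbol with 10699 and 87 UMIs and reads shared between them may have been dropped or split. In thyrotroph-like cells Tshb stood at 7800 CPM and Cga at 45153 CPM. Tshb was 5027 CPM with doublets kept, and by marker score Tshb was 3792 and Cga 21118 CPM.

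Hormone transcripts were also counted in classes that should lack them. Gh stood at 35183 CPM in T or NK cell-like and 43902 CPM in endothelial-like cells, and Prl at 3081 and 17578 CPM. Outside the somatotroph-like class Gh ranged from 17448 CPM in lactotroph-like to 82642 CPM in B cell-like cells. The pooled B cell-like value leans on set 2, where hormone genes made up 14.5% of UMIs, against 4.45% to 6.19% in the other sets. The Gh and Prl levels, and the ratio of Prl to Gh, differed between classes by more than counting error. They are therefore read neither as expression nor as an even background. Fshb was 22.9 CPM in T or NK cell-like cells and Lhb 5.49 CPM.

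**Figure D2:**
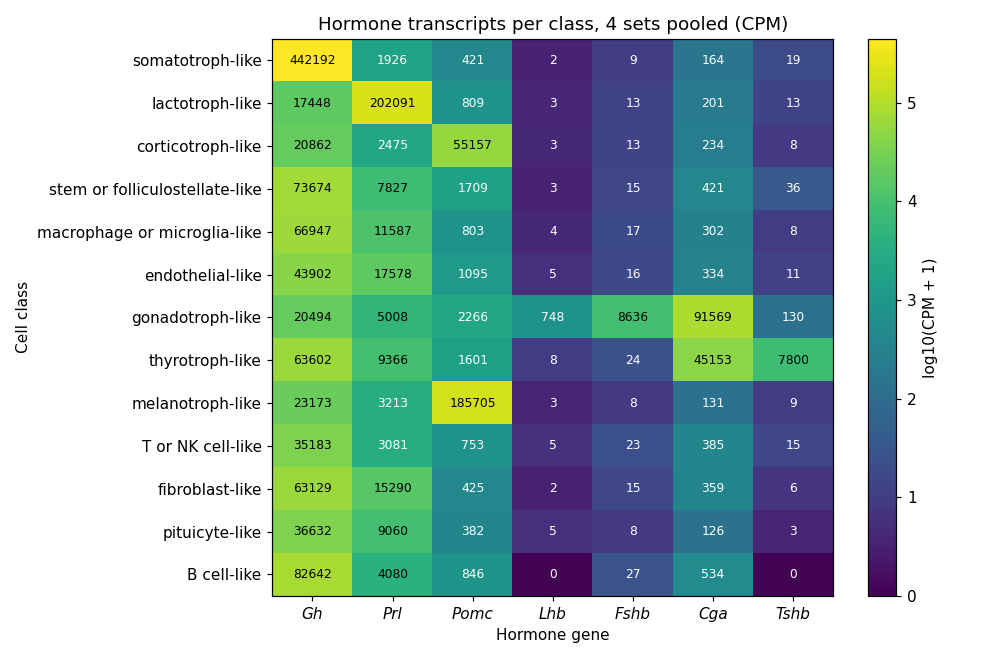
CPM of the 7 hormone genes (columns) in each cell class (rows), summed over the 4 sets, with colour on a log10(CPM + 1) scale and the CPM printed. Gh reads 442192 CPM in somatotroph-like cells and 35183 CPM in T or NK cell-like cells.

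The receptors of the releasing factors marked the matching classes. Gnrhr, the receptor of gonadotropin-releasing hormone, was 933 CPM in gonadotroph-like cells and at most 9.21 CPM in the other classes. Trhr stood at 126 CPM in thyrotroph-like, Crhr1 at 158 CPM in corticotroph-like and Ghrhr at 140 CPM in somatotroph-like cells. Drd2, the dopamine receptor, was 196 CPM in melanotroph-like cells and 92.6 CPM in lactotroph-like cells. All 5 genes were naming markers of these classes, except that Drd2 did not name the melanotroph-like class.

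The leptin receptor gene Lepr was found mainly in endothelial-like cells, at 18.3 CPM (interval 14.97 to 22.2) and from 11.6 to 22.7 CPM over the sets. In fibroblast-like cells it was 4.14 CPM. In gonadotroph-like cells 5 counts gave 0.445 CPM, and in somatotroph-like cells 11 counts gave 0.0761 CPM. The insulin receptor gene Insr was also highest in endothelial-like cells, at 276 CPM (263 to 299 over the sets), against 67.4 CPM in pituicyte-like and 64.7 CPM in thyrotroph-like cells. Of the 25 measured genes of insulin, IGF and leptin signalling, 4 peaked in endothelial-like cells in all 4 sets, and 2 with thinned counts. Igfbp3, a binding protein of the insulin-like growth factors, was 2457 CPM there and 13.0 CPM in the next class.

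Of 30 nuclear-encoded oxidative phosphorylation genes, 19 peaked in gonadotroph-like cells in all 4 sets, and 17 with hormone genes left out of library sizes. Ndufa1 was 487 CPM there (350.4 to 572 over the sets) against 172 CPM in thyrotroph-like cells. Cox7c was 626 against 382 CPM and Cox4i1 1204 against 806 CPM in corticotroph-like cells. Gonadotroph-like cells were also the deepest named class, with a median of 13654 UMIs per cell. With counts thinned to the smallest class sum, 2 members met the rule. That drop cannot decide whether depth makes the lead, since few counts remain in every class. Gapdh and Aldoa of the glycolysis list led in gonadotroph-like cells too, at 863 and 595 CPM against 632 and 417 CPM in corticotroph-like cells. The share of all genes leading in this class was not computed, so the lead is not read as particular to this list.

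Of the 22 measured genes of secretory granules and hormone processing, 6 peaked in gonadotroph-like cells. Scg2, a granin, was 22462 CPM there against 2220 CPM in thyrotroph-like cells. Pcsk1, a prohormone convertase, was 728 against 173 CPM and Chga 6405 against 3129 CPM. Vgf was highest in corticotroph-like cells, at 116 CPM. Of the gonadotroph function list, 7 of 22 genes peaked in gonadotroph-like cells, but 6 of these were naming markers. Pitx1 was the other, at 626 CPM. In the same list 5 genes peaked in stem or folliculostellate-like cells, 3 with doublets kept and 1 with thinned counts.

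Of 23 measured genes of fatty acid oxidation and PPAR targets, 14 kept a peak class in all 4 sets. In stem or folliculostellate-like cells 6 peaked, among them the acyl-CoA dehydrogenase genes Acadl, Acadm and Acadvl. The 5 in macrophage or microglia-like cells (Cd36, Plin2, Ppard, Pparg and Ucp2) encode no enzyme of beta-oxidation. With thinned counts 2 peaked in each of these classes, and with equal cells per set 2 in macrophage or microglia-like cells. With hormone genes left out of library sizes, Cpt2 peaked in somatotroph-like and Hadhb in gonadotroph-like cells. Pdk4, which inhibits pyruvate dehydrogenase, was 212 CPM in stem or folliculostellate-like cells against 14.9 CPM in somatotroph-like cells, or 231 against 26.8 CPM with hormone genes left out of library sizes. Plin2, a lipid droplet coat protein, was 584 CPM in macrophage or microglia-like cells against 46.3 CPM in endothelial-like cells. Of 18 fatty acid synthesis genes, 3 peaked in stem or folliculostellate-like cells, and 1 with thinned counts. Of 19 cholesterol synthesis genes, 3 kept a peak class in all 4 sets, 2 of them in thyrotroph-like cells. That count of 2 was 6 without set 2, 5 without set 3, 1 with doublets kept and 0 by marker score, with the stricter filter or with thinned counts. With hormone-free library sizes it was 0 as well, and Dhcr7 and Lss peaked in somatotroph-like cells.

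Of 22 measured inflammation genes, 9 peaked in macrophage or microglia-like cells. Il1b was 1741 CPM there against 26.1 CPM in endothelial-like cells, and Cxcl2 was 1895 CPM, from 1453 to 3141 CPM over the sets. Cxcl1 and Il6 peaked in stem or folliculostellate-like cells, at 566 and 60.9 CPM. Of 23 interferon response and antigen presentation genes, 6 peaked in endothelial-like cells, with Ifit1 at 317 CPM, 6 in T or NK cell-like cells, with H2-K1 at 3275 CPM, and 4 in macrophage or microglia-like cells. By marker score none peaked in T or NK cell-like and 8 in macrophage or microglia-like cells. In T or NK cell-like cells H2-K1 was then 1565 CPM, and 2084 CPM with doublets kept. With thinned counts 3 peaked in endothelial-like and 2 in T or NK cell-like cells. Of 25 oxidative stress genes, 7 peaked in macrophage or microglia-like cells, with the ferritin gene Ftl1 at 5974 CPM. Hormone genes held 44.5% of somatotroph-like UMIs, and without them in library sizes Keap1, Nqo1 and Srxn1 peaked in somatotroph-like cells. Of 22 autophagy and lysosome genes, 7 peaked in macrophage or microglia-like cells as well, with the protease gene Ctsd at 3666 CPM. Of 23 extracellular matrix genes, 15 peaked in fibroblast-like cells, 11 of them not naming markers, with Col3a1 at 717 CPM, or 357 CPM by marker score.

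Of 28 immediate early genes, which cell dissociation also induces, 5 peaked in stem or folliculostellate-like and 3 in corticotroph-like cells, against 11 and 3 without set 4 and 5 in corticotroph-like cells without set 2. With doublets kept or with thinned counts 3 peaked in stem or folliculostellate-like cells. Junb was 5826 CPM in corticotroph-like cells and Atf3 3900 CPM in stem or folliculostellate-like cells. Of 14 heat shock genes 4 kept a peak class, 2 of them in endothelial-like cells, with Hspa1b at 2050 CPM there. With hormone-free library sizes 6 kept a peak class, among them Dnaja1 and Hspe1 in somatotroph-like cells. Without set 1, 4 peaked in endothelial-like cells, and 1 did by marker score, with the stricter filter or with thinned counts. Hspa1b was lower in set 1 than in every other set by 0.5 or more on the log2 scale in 6 of 9 classes. It peaked in endothelial-like cells with set 1 included, so its level there does not account for the rise to 4. In 1 of the 3 somatotroph-like clusters, of 4478 cells, the leading genes included Idi1, Hmgcs1, Dnaja4, Dnajb1, Ppp1r3c, Slc5a3 and Egr2.

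**Figure D3:**
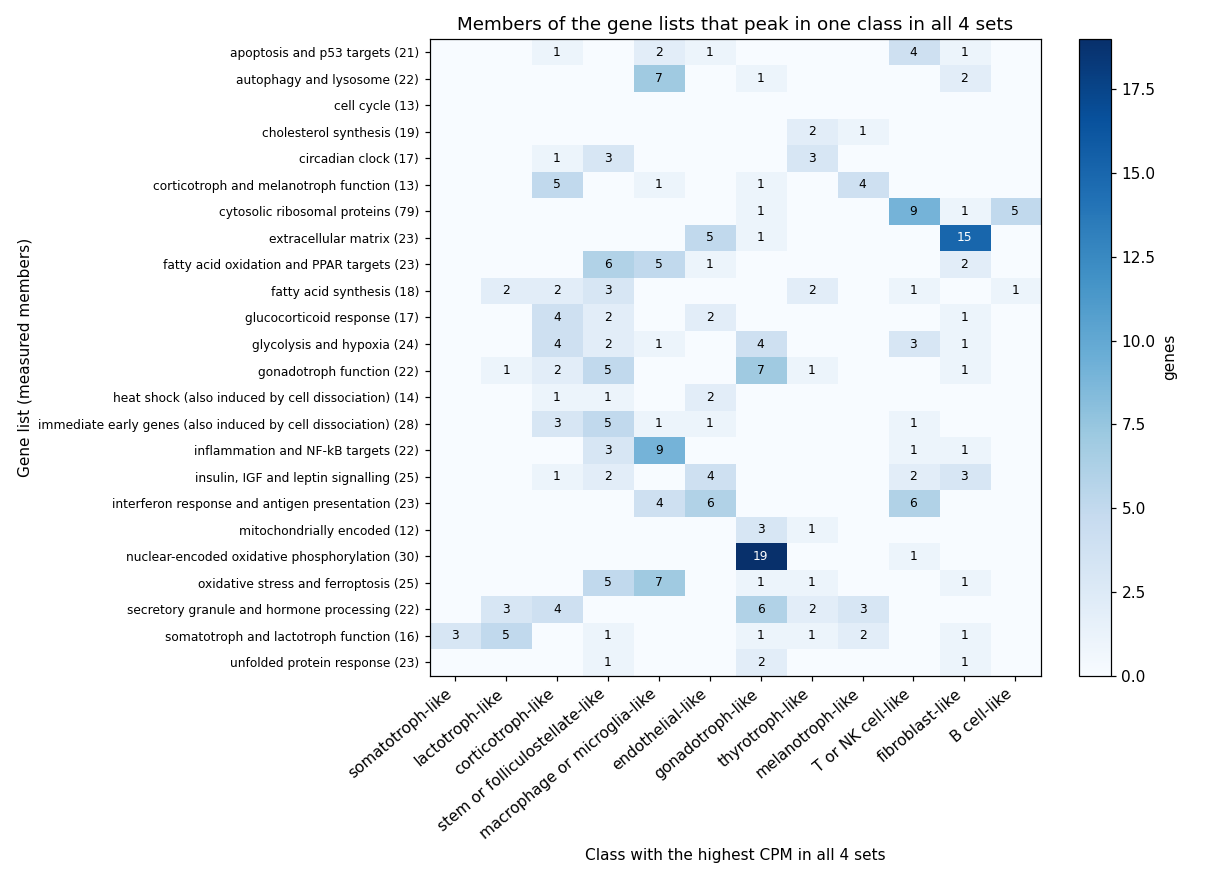
Number of members of each gene list (rows, measured members in brackets) with their highest CPM in the same class (columns) in all 4 sets. The largest entries are 19 oxidative phosphorylation genes in gonadotroph-like cells and 15 extracellular matrix genes in fibroblast-like cells.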

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

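Barcodes in 3 unnamed clusters entered no class. Unnamed cluster 8 held 2806 cells (7.79%), with 811, 661, 668 and 666 cells in sets 1 to 4. Unnamed cluster 13 held 154 cells (0.428%) and was led by the neutrophil genes S100a9 (2407 CPM) and S100a8 (1253 CPM), but had only 1 marker past the naming thresholds. Unnamed cluster 20 held 99 cells (0.275%) with a median of 17090 UMIs and markers of both stem or folliculostellate-like and endothelial-like cells.

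Cluster 8 had a median of 1386.5 UMIs and 6.15% mitochondrial UMIs, and mitochondrial genes led it. Droplets holding only free RNA are a possible explanation. Their Prl to Gh ratio would vary as binomial sampling allows, yet the dispersion ratio was 272. That does not decide, because endothelial-like (228) and macrophage or microglia-like cells (237) also exceeded the bound of 5 set in advance, as did T or NK cell-like cells (13.3). Damaged hormone cells would carry a hormone at 50% or more of the class share in at least 70% of barcodes. In cluster 8, 39.5% did (37.6 to 41.3). This bound cannot separate the explanations well, because for Gh it was 22.1% of UMIs, under the Gh share of all kept cells (24.0%). Free RNA of that average make-up would pass it too, and 888 barcodes passed on Gh. Both explanations stay open, and no biological explanation was tested.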

How the results depend on the processing

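Shares of the 6 hormone classes moved beyond their counting interval under most alternatives. Of hormone classes alone, somatotroph-, lactotroph-, corticotroph-, gonadotroph-, thyrotroph- and melanotroph-like cells made up 50.9%, 31.3%, 9.71%, 3.21%, 2.48% and 2.44%, by the smaller denominator. With doublets kept, the first 5 were 37.0%, 24.1%, 7.60%, 2.11% and 2.50%. With the stricter cell filter they were 43.1%, 24.9%, 7.83%, 1.90% and 2.52%. By marker score all 6 were 26.1%, 19.1%, 6.94%, 2.81%, 4.60% and 2.44%. At resolution 0.5 gonadotroph-like cells were 4.24%. Leaving out each set gave ranges of 37.6% to 38.7%, 22.6% to 24.7%, 6.46% to 7.63%, 1.83% to 2.78%, 1.54% to 2.02% and 1.47% to 2.07%. Apart from the smaller denominator and the merged class at resolution 0.5, the cause was not tested.

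The counts of genes peaking in the leading class of a list, whose alternatives were chosen after seeing the data, stayed within 1.5 times for the oxidative phosphorylation, extracellular matrix, inflammation and fatty acid oxidation and PPAR target lists, except when counts were thinned. Then 2 oxidative phosphorylation and 2 fatty acid oxidation genes met the rule. Thinning to 43791 UMIs leaves few counts, but at that depth 13 extracellular matrix and 9 inflammation genes still met it, against 15 and 9 before. The lead of named genes over the next class was 1.49 to 2.84 times for oxidative phosphorylation in gonadotroph-like cells. It was 6.82 to 15.7 times for extracellular matrix in fibroblast-like cells. At full depth, 14 of 100 simulated genes raised 1.5-fold met the rule, against 86 of 100 raised 4.0-fold. Thinning therefore cannot separate an effect of depth on the lead from the loss of small leads. Why the lists differed was not tested. Among 101 named genes, doublets moved 6 levels by over 1.5 times, the stricter filter 3 and marker scores 20. Hormone-free library sizes raise all genes of a class by the same factor, here from 1.04 to 1.80 times. They moved 1 level by over 1.5 times, Ghsr in somatotroph-like cells, the class with the largest hormone share. That count follows from the hormone shares and does not measure how stable the levels are. The moved genes lay mostly in T or NK cell-, B cell- and fibroblast-like cells. Of 552 other list counts, 383 stayed within 1.5 times and 169 did not, some of these because the hormone-free setting drops hormone genes from the lists. Leaving out single sets kept 339 of 368. Neither total scores a class in which no member of a list peaked in the main setting. Gains in such a class are left out, for example Keap1, Nqo1 and Srxn1 in somatotroph-like cells with hormone-free library sizes. Depth limits the B cell-like class most.

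No paired analysis was possible because no barcode was tied to a library or its replicate number. For the same reason the planned edgeR, camera and fry fits, their normalizations, low-count filters and blocks were not run. Nor were the permutation of libraries and the interaction of diet with class. No DESeq2 or other limma fit was run in their place.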

Other observations

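The tests on the mitochondrial genes, and the choice of every gene named here, were made after the values were seen. The sets carry no diet label, so their values are listed without grouping. In macrophage or microglia-like cells the interferon-induced gene Ifit2 was 61.9, 314, 37.8 and 48.6 CPM in sets 1 to 4, and Rsad2 was 159, 357, 104 and 155 CPM. In stem or folliculostellate-like cells Tnfaip3, an inhibitor of NF-kB signalling, was 10.9, 92.4, 15.4 and 15.6 CPM, and Nfkbia was 406, 1105, 416 and 330.2 CPM. The heat shock gene Hspa1b in somatotroph-like cells was 491, 895, 722 and 797 CPM. Pituicyte-like cells numbered 94, 6, 55 and 72 and melanotroph-like cells 262, 100, 116 and 182.

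Of 21 apoptosis genes 4 peaked in T or NK cell-like cells, with Bcl2 at 471 CPM, but 1 with doublets kept or by marker score, where Bcl2 was 312 and 223 CPM, and 2 with thinned counts. Of 17 circadian clock genes 3 peaked in thyrotroph-like cells (5 without set 1, 1 by marker score or with thinned counts), with Hlf at 469 CPM or 263 CPM by marker score, and 3 in stem or folliculostellate-like cells, with Nr1d1 at 577 CPM (5 by marker score). Of 17 glucocorticoid response genes 4 peaked in corticotroph-like cells, with Cebpd at 1573 CPM, and 1 with thinned counts. Of 24 glycolysis and hypoxia genes 4 peaked in gonadotroph-like cells, with Vegfa at 181 CPM, 4 in corticotroph-like cells, with Slc2a1 at 58.0 CPM, and 3 in T or NK cell-like cells. With thinned counts these counts were 2, 0 and 0. With hormone-free library sizes 2 peaked in corticotroph-like cells, and with doublets kept or by marker score 1 in T or NK cell-like cells. Of 79 ribosomal protein genes 9 peaked in T or NK cell-like and 5 in B cell-like cells, but these counts ranged from 0 to 58 and from 0 to 28 over the alternatives. Of 12 mitochondrially encoded genes 3 peaked in gonadotroph-like cells, 5 with the stricter filter and 10 by marker score. Of 23 unfolded protein response genes 2 peaked in gonadotroph-like cells, with Pdia3 at 1089 CPM, but 8 without set 1 and 5 by marker score. With hormone-free library sizes Asns and Ern1 peaked in somatotroph-like cells. No cell cycle gene kept a peak class. Of 16 somatotroph and lactotroph genes 5 peaked in lactotroph-like cells, with Pou1f1 at 536 CPM, 3 with the stricter filter and 1 with thinned counts. Of these 5, 4 were not naming markers. With Gh and Prl left out of the list and of library sizes, 3 of 14 did, as Prl was no longer counted and Neurod4 peaked in somatotroph-like cells. Of 13 corticotroph and melanotroph genes 5 peaked in corticotroph-like cells, and 3 with thinned counts. Only 2 of the 5 were not naming markers, Neurod1 (243 CPM) and Nr3c1. Ddx3y was 108 CPM and Xist 0.0900 CPM in somatotroph-like cells. The mice were male, per the series description.

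Across 9 classes, 20 of 4692 tested genes stood apart in set 4, by 0.5 or more on the log2 scale from every other set, in at least 5 classes, against 2, 4 and 0 genes in sets 1 to 3. In somatotroph-like cells Rps10 was 215, 236, 201 and 475 CPM in sets 1 to 4, and Gpx4 102, 94.6, 101 and 47.6 CPM. Reads shared between near-identical genes are a candidate explanation: 90% of the 20 genes (68.3 to 98.8) share 10% or more of the 75-base stretches of their 3 prime ends with another annotated gene, against 8.59% of all tested genes and 13.5% of genes matched on expression. A linked strain variant stays open: 20% of the genes lie on 1 chromosome, with an interval (5.73 to 43.7) too wide to decide. Whether shared reads were counted differently in set 4, and whether diet plays a part, was not tested.

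The 7 mitochondrial protein genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3, mt-Nd4l and mt-Nd6 were under 100 CPM, while mt-Cytb was 4664 CPM. Overlap with a neighbouring gene cannot explain them all, since 5 of the 7 overlap a same-strand neighbour over under 5% of their length. Reads shared with nuclear pseudogene copies may contribute: the median share of 75-base stretches found in another transcript was 98.7%, against 1.29% in the other 6 genes. But mt-Atp8 and mt-Nd6 were low with a share of 0%, and mt-Co1 had 95.1% at 924 CPM. Only annotated transcripts were compared, so a share of 0% does not show that a gene has no nuclear copy. Shared reads therefore cannot be told apart from other causes, such as real differences in transcript level. Apart from gene overlap, no other cause was tested. The mitochondrial percentages used to filter cells are read with that limit.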
